A study of Homo sapiens with 6 samples.

How the data were processed

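RNA from SH-SY5Y neuroblastoma cells was profiled on 6 one-colour human expression arrays of the Affymetrix PrimeView type, 3 for cells given 3 µM endosulfan for 24 h and 3 for control cells. Per the labels' protocols, cells were grown in MEM and F12 medium with serum, total RNA was extracted with a column kit, and biotin-labelled cRNA was made from it. The authors deposited 1 table of log2 values for all arrays. Per the submitters' processing notes the values come from Affymetrix Expression Console with RMA, a method that corrects background, normalizes the arrays to shared quantiles and summarises probes into a log2 value per probe set. Versions, options and filters are not given in the sources used here. RMA's quantile step forces the arrays to nearly the same distribution, so a shift of most transcripts in 1 direction is removed. The deposited log2 values ran from 1.95 to 14.4, and the arrays' upper quartiles from 6.58 to 6.74. Scanner intensities were not used here, so no call of signal above background could be made and no probe set was removed as dim.

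Groups came from the labels' agent field and replicate numbers from the sample titles. The table had 49395 rows. The 102 control probe sets of the array were set aside and used to describe array quality, and the other 49293 were tested. By the platform annotation given with the table, 44988 probe sets named 1 gene, 1832 several and 2473 none. Gene IDs of 44961 of the one-gene probe sets were found in a RefSeq table of assembly GRCh38.p14, used for names and gene lengths alone, and no symbol needed an update. No coordinates are given, since no build was named. At gene level each of 18132 genes was represented by the one-gene probe set with the highest mean over the 6 arrays, and 11734 genes had several probe sets to choose from.

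The comparison was endosulfan against control, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 6 arrays without further normalization. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets or over all genes, and the threshold was an adjusted p below 0.05, also with a fold change of at least 1.5. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over 38 lists covering stress responses, xenobiotic and lipid metabolism, cell cycle, energy metabolism, signalling, neuronal and neuroblastoma genes, protein and RNA handling and markers of other cell types. These lists held 1092 entries, of which 1001 were measured. A camera test with an estimated correlation and limma's fry, which tests whether a list moves one way on balance without comparing it with other genes, were alternatives. Array quality measures were compared with two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

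The groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined. By that rule the genes named in each direction are the 15 with the largest change among those past the threshold with groups that do not overlap, or, where fewer pass, a list filled to 10 by smallest unadjusted p. Added to these are up to 4 members past the threshold in each list and, for a list that passes, up to 4 further members by smallest p. Probe sets with several genes or none and uncharacterised loci are not named. Fixed alternatives were the replicate number as a block, a further quantile normalization, centring on array medians, the probe sets above the median level alone, a mean-variance trend with robust moderation, array weights, a linear model without moderation, the mean of a gene's probe sets, a fold limit of 2, the other set tests and leaving out each array in turn. Chosen after the data were seen were a fit without control 1 and endosulfan 1, a fit with the mean poly-A spike-in level as a covariate and a fit of control 2, endosulfan 1 and endosulfan 2 alone.

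The fit was tested on simulated data, made for the endosulfan comparison with 50 features changed at each size. Over 49293 probe sets it recovered 18%, 54%, 92% and 96% at log2 changes of 0.585, 1, 2 and 3, with 9 false calls among 139. Over 18132 genes it recovered 22%, 74%, 96% and 100%, with 6 false calls among 152. A simulated list of 30 genes shifted by 0.4 was called, and 0 of 37 other lists were. The simulation draws independent noise and does not hold the gradient that runs through the real arrays.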

Results

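Gene expression was measured in SH-SY5Y cells, an established human neuroblastoma line with neuron-like and catecholaminergic features. The cells were given endosulfan, an organochlorine insecticide that blocks GABA-gated chloride channels, at 3 µM for 24 h, a dose that the labels place below the LC50. The question was which transcripts differ between exposed and control cells. There were 3 endosulfan and 3 control arrays, described in the labels as biological replicates with no culture, passage or day named. What the control cells received is not given in the sources used here. Each array gave a log2 RMA value for 49395 probe sets. The array medians lay between 4.89 and 4.94, and no pair among the 15 pairs of arrays held identical values. Pearson's r across probe sets, which are not independent replicates, was 0.987 to 0.995 between control arrays, 0.985 to 0.993 between endosulfan arrays and 0.964 to 0.994 between the groups. For arrays like these, their number limits the precision.

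The arrays' own control probe sets differed in level. The bacterial poly-A transcripts that are spiked into the RNA before labelling had a mean of 6.62 ± 1.06 (SD, n = 3, log2) in control arrays and 8.21 ± 0.60 (SD, n = 3) in endosulfan arrays. Control 1 and control 3 were at 6.19 and 5.84, whereas control 2, endosulfan 1 and endosulfan 2 were nearly level at 7.83, 7.90 and 7.82, and endosulfan 3 was at 8.90. With 3 arrays against 3, the smallest two-sided p of an exact permutation test is 0.1, so no single measure of this kind could pass 0.05. The exact permutation p was 0.2 for these spike-ins. The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA integrity, was 0.75 ± 0.06 (SD, n = 3) in control and 0.84 ± 0.04 (SD, n = 3) in endosulfan arrays, with an exact permutation p of 0.1. The same difference for beta-actin was 3.59 ± 0.07 (SD, n = 3) and 3.67 ± 0.10 (SD, n = 3), with an exact permutation p of 0.3. The first principal component held 63.9% of the variance and ran from -71.6 in control 1 to 61.8 in endosulfan 1, with control 2 at -2.33 beside endosulfan 2 at -1.81. Every control array lay below every endosulfan array on it, with an exact permutation p of 0.1.

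**Figure D1:**
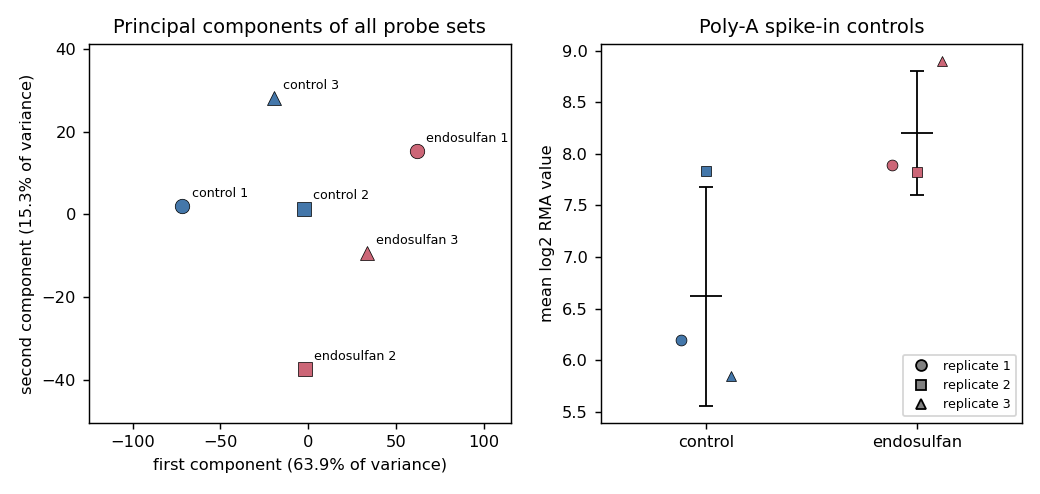
Left, the first and second principal components of the 6 arrays over all probe sets, with control arrays in blue and endosulfan arrays in red. Right, the mean log2 RMA value of the poly-A spike-in controls per array, with the group mean and SD as a black bar; control 1 and control 3 lie at 6.19 and 5.84, below the other arrays.

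Some, but not all, probe sets of 2 immediate early transcription factors, EGR1 and FOS, were higher in endosulfan-exposed cells. EGR1, a zinc finger factor that growth factor and stress signalling induces within minutes, rose 3.33-fold, from 6.78 ± 0.07 in control to 8.52 ± 0.14 in endosulfan arrays (log2, SD, n = 3 each). FOS, a subunit of the AP-1 transcription factor, rose 6.58-fold on its most responsive probe set, from 4.03 ± 0.11 to 6.75 ± 0.38 (log2, SD, n = 3 each). In both cases every endosulfan array lay above every control array. These were the changes that passed the test over 49293 probe sets: 4 probe sets were higher and 0 lower with limma at a Benjamini-Hochberg adjusted p below 0.05, namely 3 of the 6 probe sets of EGR1 and 1 of the 4 of FOS. All 4 also exceeded the fold limit of 1.5. The log2 fold changes of the 3 EGR1 probe sets were 1.74 ± 0.11 (SE), 1.59 ± 0.11 (SE) and 1.48 ± 0.12 (SE), with limma and Benjamini-Hochberg adjusted p of 0.00913, 0.00913 and 0.0277, and that of the FOS probe set was 2.72 ± 0.19 (SE), with an adjusted p of 0.00913.

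The probe sets of each gene did not move alike. The 6 probe sets of EGR1 had log2 fold changes from 0.05 to 1.74. The remaining 3 probe sets of FOS, named here after their values were seen, had log2 fold changes of 1.53, 0.56 and 0.29. The brightest of them, which stands for FOS at gene level, was the one at 0.29. Its groups overlapped, with a limma and Benjamini-Hochberg adjusted p of 0.355 over all probe sets. The FOS probe set that passed was dim in control arrays, with a mean of 4.03 below the array medians of 4.89 to 4.94. At gene level, with the brightest probe set for each of 18132 genes, EGR1 was therefore the 1 gene past the threshold, with a limma and Benjamini-Hochberg adjusted p of 0.0103, and no gene was lower. At an unadjusted p below 0.05 there were 1204 genes higher and 1899 lower with limma, where chance alone gives 906.6 in all, and the next adjusted p after EGR1 was 0.196. That total of 3103 genes ranged from 1618 to 4091 with 1 array left out and was 301 with the spike-in level as a covariate, a fit with 1 residual degree of freedom fewer and a covariate that itself differs between the groups, and a split of the arrays that sets control 1, control 3 and endosulfan 2 against the rest gave 3169. The groups of 22.6% of the genes did not overlap, against 10% by chance. Among the 3 arrays with like spike-in levels, EGR1 was at 6.73 in control 2 against 8.67 and 8.48 in endosulfan 1 and 2, and the FOS probe set was at 4.14 against 7.18 and 6.52. EGR1 at gene level lost its call when any 1 array was left out, with adjusted p from 0.0526 to 0.134 and log2 fold changes from 1.66 to 1.80, and the count of probe sets ranged from 0 to 7. The call of EGR1 also ended with the replicate number as a block. It ended too with the mean of its probe sets, at a log2 fold change of 0.92 and an adjusted p of 0.0537, and with a linear model without moderation, at an adjusted p of 0.324. The call ended as well with the spike-in level as a covariate, at 1.86 and an adjusted p of 0.442, and without control 1 and endosulfan 1, at 1.64 and an adjusted p of 0.104. Among the 3 arrays with like spike-in levels, 1 of them a control, EGR1's log2 fold change was 1.85, and arrays so few cannot decide a call. With limma's array weights, which rested mainly on control 3 and endosulfan 3, 5915 genes passed.

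**Figure D2:**
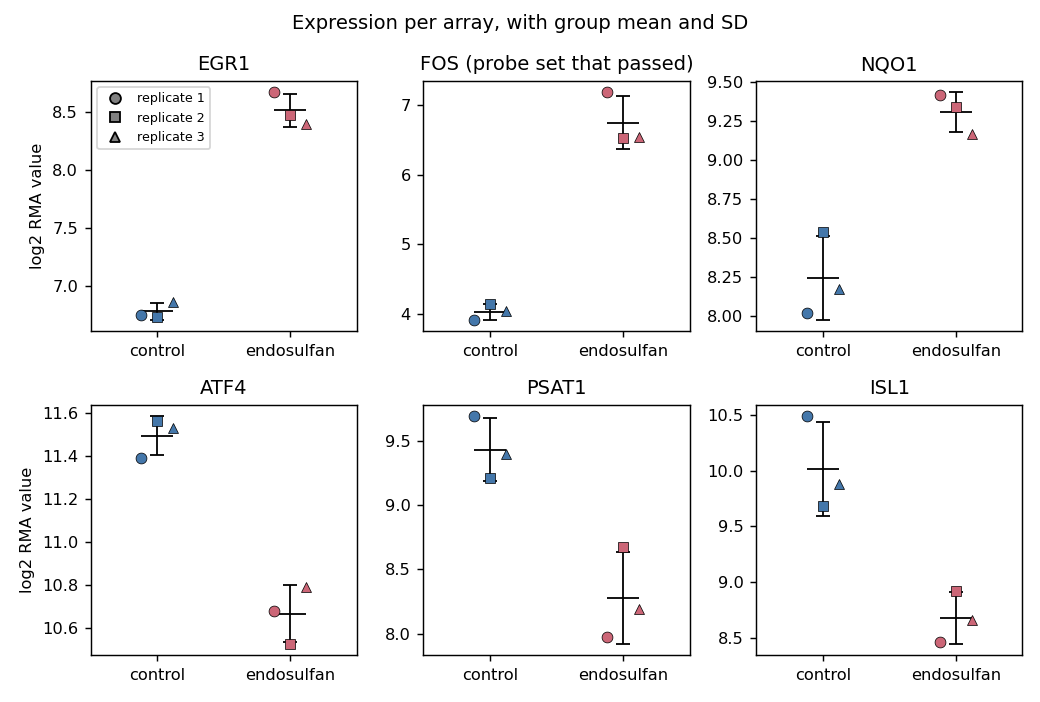
Log2 RMA value per array of EGR1, FOS (the probe set that passed), NQO1, ATF4, PSAT1 and ISL1, with each replicate as a symbol and the group mean and SD as a black bar. EGR1 lies at 6.73 to 6.86 in control and 8.40 to 8.67 in endosulfan arrays, and in each panel the arrays of the groups do not overlap.

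The genes next in rank in the higher direction did not pass the threshold, and the limma and Benjamini-Hochberg adjusted p was 0.196 for each of the 9 that filled the list. NQO1, a quinone reductase and a target of the oxidative stress factor NRF2, was at 8.24 ± 0.27 in control and 9.30 ± 0.13 in endosulfan arrays (log2, SD, n = 3 each), a 2.09-fold difference with a log2 fold change of 1.06 ± 0.16 (SE). CRLS1, the cardiolipin synthase of mitochondria, was at 8.42 and 9.43, and METRNL, a secreted meteorin-like protein, at 6.48 and 7.46. The bHLH factor TCF15 was at 7.78 and 8.54, and the Mediator subunit MED30 at 9.12 and 9.85. CDC37L1, which binds HSP90, was at 4.86 and 6.12. PPIL6, of the peptidylprolyl isomerase family, was at 4.89 and 6.22, the SUMO ligase ZNF451 at 4.89 and 5.55, and the histone H2B gene H2BC10 at 3.02 and 3.69. The 9 differences lay between 1.58-fold and 2.51-fold.

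In the lower direction 0 genes passed, and the 10 genes with the smallest unadjusted p, which fill the list, all had a limma and Benjamini-Hochberg adjusted p of 0.196. Their differences lay between 1.78-fold and 2.94-fold. ATF4, the central transcription factor of the integrated stress response, was at 11.50 ± 0.09 in control and 10.67 ± 0.13 in endosulfan arrays (log2, SD, n = 3 each), a log2 fold change of -0.83 ± 0.12 (SE). The homeobox factor DLX5 was at 6.75 ± 0.08 and 5.87 ± 0.04 (SD, n = 3 each). The Mediator kinase CDK19 had a log2 fold change of -1.56, RAB3GAP2, a subunit of the Rab3 GTPase-activating complex, of -1.31, and the RNA-binding protein FAM120A of -1.42. The zinc finger repressor ZNF91 was at -1.36, PRR16 at -0.84, the synaptic organiser CBLN2 at -0.83, the molybdopterin synthase MOCS2 at -0.88 and the G protein regulator RGS16 at -0.95. Of the 35 genes named by the rule, 30 have several probe sets, and in 13 of these some probe sets had the opposite sign, namely DLX5, CDK19, ZNF91, FAM120A, CBLN2, RGS16, DCX, NUSAP1, PRC1 and SATB1 in the lower and CRLS1, PPIL6 and ZNF451 in the higher direction. With the mean of each gene's probe sets, 20 of the 35 log2 fold changes were smaller by over 1.5 times, among them DLX5 at -0.29, CDK19 at -0.48, RAB3GAP2 at -0.65, PPIL6 at 0.43 and ZNF451 at 0.15.

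Of the 38 gene lists fixed in advance, 4 fell and none rose with limma's camera test at the preset inter-gene correlation of 0.01. With an estimated correlation none of the 4 passed: the adjusted p was 0.867 for the mitotic list and 0.570 for each of the others. No member of the 4 lists was past the threshold over all genes, so the values of single members that follow did not pass.

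The G2/M and mitosis list, with 36 genes of chromosome segregation and cytokinesis, had a median log2 fold change of -0.49 and a limma camera adjusted p of 9.86e-06 after Benjamini-Hochberg adjustment. There were 29 members on the lower and 7 on the higher side, 13 at an unadjusted p below 0.05, all lower, and 0 when adjusted over the list alone. The proliferation marker MKI67 was at 7.73 ± 0.56 in control and 6.50 ± 0.35 in endosulfan arrays (log2, SD, n = 3 each), and PRC1, CENPF and NUSAP1, which act at the spindle and kinetochore, had log2 fold changes of -1.25, -0.94 and -1.03. The groups overlapped in the mean of this list: relative to the mean of the 6 arrays, endosulfan 2 was at 0.13 and control 2 at -0.02. Among the 3 arrays with like spike-in levels, a selection made after the data were seen that holds 1 control array, control 2 thus lay between endosulfan 1, at -0.51, and endosulfan 2. The median of the list was -0.32 without endosulfan replicate 1 and -0.18 with the spike-in level as a covariate. PRC1 and NUSAP1 each had 1 probe set of the opposite sign.

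The neuronal cytoskeleton and axon growth list, with 33 genes measured, had a median log2 fold change of -0.18 and a limma camera adjusted p of 5.18e-05 after Benjamini-Hochberg adjustment. There were 27 members on the lower and 6 on the higher side, 11 lower at an unadjusted p below 0.05 and 7 lower when adjusted over the list alone. DCX, a microtubule-binding protein of migrating neurons, was at 9.28 ± 0.53 in control and 7.73 ± 0.42 in endosulfan arrays (log2, SD, n = 3 each). The neuronal RNA-binding protein ELAVL4, the neurofilament protein INA and the growth cone protein STMN2 had log2 fold changes of -1.09, -1.03 and -1.05. Of the 5 probe sets of DCX, 4 were lower. Among the 3 arrays with like spike-in levels, with 1 control array, the list mean was at 0.05 in control 2 and at -0.32 and -0.05 in endosulfan 1 and 2, relative to the 6 arrays.

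The ATF4 target list of the integrated stress response, which controls amino acid synthesis and import, had 32 genes measured, a median log2 fold change of -0.12 and a limma camera adjusted p of 0.0016 after Benjamini-Hochberg adjustment. There were 21 members on the lower and 11 on the higher side, 10 lower and 1 higher at an unadjusted p below 0.05, and 7 lower when adjusted over the list alone. Besides ATF4 itself, PSAT1, an enzyme of serine synthesis, was at 9.43 ± 0.24 in control and 8.28 ± 0.36 in endosulfan arrays, and the glycyl-tRNA synthetase GARS1 at 10.28 ± 0.66 and 8.65 ± 0.36 (log2, SD, n = 3 each). The lipoprotein receptor VLDLR had a log2 fold change of -1.14. Among the 3 arrays with like spike-in levels, with 1 control array, the list mean was at 0.15 in control 2 and at -0.15 and -0.12 in endosulfan 1 and 2, relative to the 6 arrays. The call was lost without control replicate 2, at an adjusted p of 0.0653, and the median was -0.04 with the mean of each gene's probe sets and -0.24 with the spike-in level as a covariate.

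The list of adrenergic neuroblast transcription factors, which maintain the sympathetic identity of neuroblastoma cells, had 16 genes measured, a median log2 fold change of -0.14 and a limma camera adjusted p of 0.0348 after Benjamini-Hochberg adjustment. There were 10 members on the lower and 6 on the higher side, 6 lower and 1 higher at an unadjusted p below 0.05, and 6 lower when adjusted over the list alone. The LIM homeodomain factor ISL1 was at 10.02 ± 0.42 in control and 8.68 ± 0.23 in endosulfan arrays (log2, SD, n = 3 each). TFAP2B, MYCN and the chromatin organiser SATB1 had log2 fold changes of -0.73, -0.48 and -1.11. Of the 3 probe sets of SATB1, 2 were lower. Among the 3 arrays with like spike-in levels, with 1 control array, the list mean was at 0.10 in control 2 and at -0.25 and -0.09 in endosulfan 1 and 2, relative to the 6 arrays. The call was lost without control replicate 2, with array weights and with the linear model without moderation, at adjusted p of 0.098, 0.114 and 0.0906, and this was the 1 list that limma's fry test called, with an adjusted p of 0.00601. With the probe sets above the median level alone, the median of the list was -0.35.

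**Figure D3:**
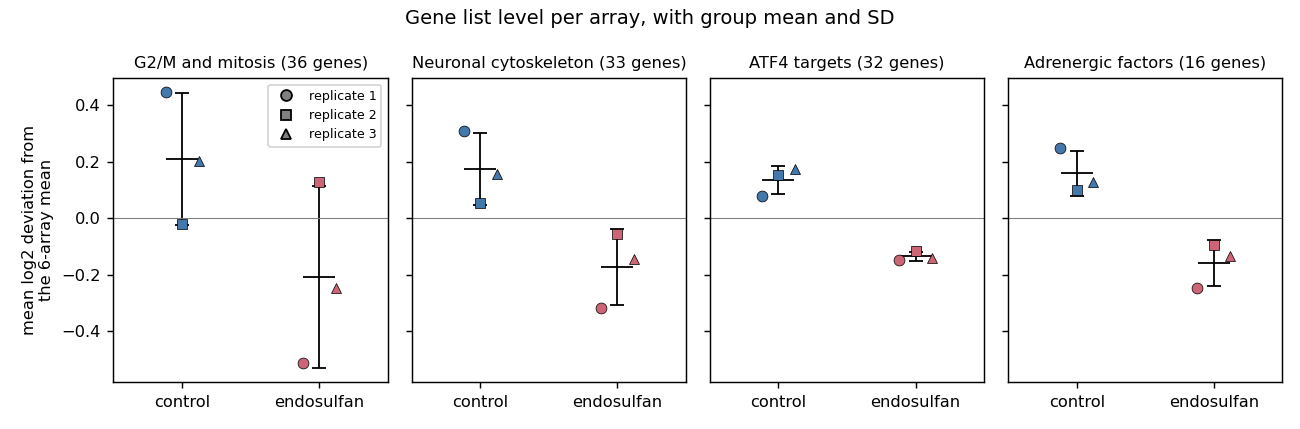
Mean log2 deviation of each lower gene list from its mean over the 6 arrays, per array, with the group mean and SD as a black bar. Control 1 and endosulfan 1 lie at the ends in the mitotic list, at 0.45 and -0.51, and in that list endosulfan 2, at 0.13, lies above control 2, at -0.02.

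The remaining 34 lists had medians between -0.10 and 0.18 and adjusted p from 0.0976 to 0.989 with limma's camera and Benjamini-Hochberg adjustment. The immediate early genes, with EGR1 as the 1 member past the threshold among 31 measured, had a median log2 fold change of 0.15 and an adjusted p of 0.22. Adjusted over the list alone, 1 member was higher and 1 lower. The interferon-stimulated genes were at 0.17 with an adjusted p of 0.0976, and the NRF2 targets at 0.13 with an adjusted p of 0.44, NQO1 being the 1 of 25 members that was higher when adjusted over the list alone. GABA receptor subunits and GABA handling genes, which include the subunits of endosulfan's known channel target, were at 0.07 with an adjusted p of 0.722, and 0 of the 24 measured members passed. The ER chaperone and unfolded protein response list was at -0.07 with an adjusted p of 0.234, p53 targets at 0.10 with an adjusted p of 0.989 and oestrogen-responsive genes at 0.10 with an adjusted p of 0.95. In the oestrogen list the mean, at -0.02, and the direction of the test had the opposite sign to the median, and the signs of median, mean and test were mixed in 10 of the 38 lists. Markers of other cell types did not pass: epithelial, haematopoietic, endothelial and Schwann or glial markers had medians of 0.12, 0.05, 0.11 and 0.16 and adjusted p of 0.305, 0.572, 0.423 and 0.302. The calls depended on the setting: 2 lists passed without control replicate 2 and 8 without endosulfan replicate 2. Lists called higher under a fixed alternative were cholesterol synthesis with the probe sets above the median level alone (adjusted p 0.0436), interferon-stimulated genes in that setting (0.0464), with array weights (0.0384) and without endosulfan replicate 2 (0.0285), immediate early genes without endosulfan replicate 2 (0.0371), and NRF2 targets and glycolysis without control replicate 1 (0.0373 and 0.0493). Further lists called lower were core spliceosome proteins with array weights (0.048), with the mean of a gene's probe sets (0.0129) and without endosulfan replicate 2 (0.00183), and G1/S and DNA replication genes without endosulfan replicate 2 (0.00829).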

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

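The tests that use the poly-A spike-ins, the within-group axis and the counts of probe sets and genes over other splits of the arrays were chosen after those results had been seen. The levels of 3 kinds of control probe sets, which the comparison of transcripts does not use, were higher in the endosulfan arrays. The poly-A spike-ins were higher by 1.59 on the log2 scale, from 6.62 ± 1.06 to 8.21 ± 0.60 (SD, n = 3 each, exact permutation p = 0.2). The hybridisation controls, added after labelling, were higher by 0.633, from 10.29 ± 0.29 to 10.93 ± 0.18 (SD, n = 3 each, exact permutation p = 0.1, the smallest that these arrays can give). The 18S ribosomal RNA probe sets were higher by 0.532, from 11.45 ± 0.44 to 11.99 ± 0.43 (SD, n = 3 each, exact permutation p = 0.3).

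The first pattern is the rise of EGR1 and of the FOS probe set that passed. If the rise came from the gradient that most genes share, it should vanish with the first principal component of the other genes as a covariate. It did not vanish: the endosulfan coefficient was 1.65 for EGR1 (95% interval 1.20 to 2.11) and 2.35 for FOS (1.52 to 3.17). With the spike-in level as a covariate the coefficients were 1.86 (1.45 to 2.27) and 2.73 (1.47 to 3.98), although EGR1 did not pass over all genes in that fit (adjusted p = 0.442). Both probe sets were picked by a test that favours a small spread within the groups, which leaves little slope for a covariate. Intervals like these were therefore likely beforehand, and they do not decide against the gradient or RNA input. The real grouping is the 1 of 10 splits of the 6 arrays that gave as many calls, with 4 probe sets, also 4 at the fold limit of 1.5, and 1 gene against 0 in the highest of the other splits, but 10 splits are too few for a share under 0.05. A response to endosulfan may underlie both rises as a hypothesis, with the gradient and RNA input not excluded. Handling of the cells at harvest, which also induces these genes, is open and untested.

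The second pattern is the fall of 4 gene lists. For the mitotic list the coefficient went from -0.42 to 0.0685 (95% interval -0.26 to 0.40) with the gradient as a covariate. With the spike-in level it went to -0.19 (-1.32 to 0.95, which also holds the unadjusted value). For the neuronal cytoskeleton list it went from -0.35 to -0.12 (-0.24 to 0.009) with the gradient and to -0.26 (-0.80 to 0.29) with the spike-in level. The gradient could account for the mitotic fall and for part of the neuronal one, whose interval only just holds no change. But the first component over all probe sets itself had a mean of -31.1 in control and 31.1 in endosulfan arrays. Such a covariate would also take up an endosulfan effect shared by many genes, so the smaller coefficients do not separate the gradient from such an effect. The spike-in level leaves the mitotic and the neuronal fall undecided. The ATF4 targets went from -0.27 to -0.30 (-0.45 to -0.15) with the gradient and to -0.27 (-0.44 to -0.10) with the spike-in level. The adrenergic factors went from -0.32 to -0.18 (-0.27 to -0.09) with the gradient, a smaller but nonzero fall. With the spike-in level they were at -0.28 (-0.63 to 0.07), which leaves them open. Both lists were picked by a test on these same arrays that favours a small spread within the groups. That can leave little slope for a covariate, so these intervals do not decide against the gradient or RNA input. Of the 10 splits of the arrays, 5 gave 4 or more lists, and the highest of the others gave 11. This points to a structure of the arrays beyond the groups, although 10 splits are too few for a share under 0.05. The split with control 1, control 3 and endosulfan 2, the lowest in spike-in level, gave 10. Control 2 was nearly level with endosulfan 2, at 7.83 against 7.82, and in its place makes the real groups, which gave 4. Endosulfan 1, at 7.90, gave 0 in that place. The list counts thus did not follow the spike-in level alone. With the spike-in level as a covariate the real groups gave 4. A lower ATF4 programme under endosulfan may be taken as a hypothesis for the ATF4 targets alone, with chance still open and the gradient and RNA input not excluded. Camera with an estimated correlation gave an adjusted p of 0.570, although the correlation estimated for this list was only 0.04. That test called no list in any of the 10 splits, so its outcome does not show that correlation among the genes explains the fall.

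The third pattern is the excess of 3103 genes at an unadjusted p below 0.05 with 1 past the threshold. The main axis of the deviations within the groups held 64.2% of their variance, and the endosulfan effect correlated with it across genes at r = 0.697. In arrays that share no sample, endosulfan 1 minus endosulfan 2 correlated with endosulfan 3 minus the controls at r = 0.527. Likewise, control 2 minus control 1 correlated with endosulfan minus control 3 at r = 0.565, with genes that are not independent replicates. These pairs lie at the ends of the within-group axis in their groups, with the order of subtraction following it, and other pairs were not tried. Genomic gene length, introns included, ran along both, with a rank correlation of -0.276 for the axis and -0.281 for the effect over 18112 genes. Transcript length was not examined, so a length-related difference in RNA or labelling is no more than an untested candidate for part of the excess. Split off with control 1 and control 3, which had the lowest spike-in levels, endosulfan 2 gave 3169 such genes. Endosulfan 1, at nearly the same spike-in level as endosulfan 2, gave 278 in that place. A treatment that moves cells along an axis they also vary on without it cannot be told apart from a technical gradient here.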

How the results depend on the processing

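The fits without control 1 and endosulfan 1, with the spike-in covariate and of the 3 arrays with like spike-in levels were chosen after the data were seen. Against 4 probe sets, 4 at the fold limit of 1.5 and 1 gene, limma's array weights gave 7101, 2788 and 5915. The weights were 5.46 for endosulfan 3 and 4.22 for control 3 at gene level, their estimation stopped short of convergence, and other splits of the arrays gave up to 3897 genes with them. The linear model without moderation gave 0, 0 and 0, the spike-in covariate 0, 0 and 0, and the fit without control 1 and endosulfan 1 gave 1, 1 and 0. The like-spike arrays, where the lone control array is assumed to vary like the endosulfan arrays, are too few for such counts to be read. The mean of a gene's probe sets gave 0 genes. Leaving out each array in turn gave 0 to 7 probe sets, 0 to 7 at the fold limit and 0 genes each time. Genes at an unadjusted p below 0.05 numbered 3103 in all, 1618 to 4091 with an array left out, and 301 with the spike-in covariate, which differs between the groups and takes up 1 residual degree of freedom.

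The replicate number as a block gave 0 probe sets, 0 at the fold limit, 0 genes and 4 lists. Deviations of same-numbered arrays within their groups correlated at -0.513, -0.403 and 0.051, and no array correlated best with its own number. The main axis within the groups held 64.2% of the variance of such deviations. Its scores were -28.6 in control 1 against 24.5 in endosulfan 1, and 18.4 in control 2 against -26.8 in endosulfan 2. The correlations cannot be separated from these positions, so they do not decide whether same-numbered samples share a culture or day.

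Against 4 lists, camera with an estimated correlation gave 0, fry 1, and the fit without control 1 and endosulfan 1 gave 7. Leaving out each array gave 2 to 8 lists, with 2 without control replicate 2 and 8 without endosulfan replicate 2. The medians of the 4 lists kept their sign under every alternative run but not their size: they ranged from -0.72 to -0.16 for the mitotic list (-0.72 to -0.32 with an array left out), from -0.24 to -0.15 for the neuronal list, from -0.27 to -0.04 for the ATF4 targets and from -0.35 to -0.10 for the adrenergic factors. Their test kept its side of the threshold in 65 of 76 cases. EGR1's log2 fold change lay between 0.92 and 1.86, with adjusted p from 0.000161 to 1.00, and that of the FOS probe set between 2.44 and 2.83, with adjusted p from 0.000465 to 1. The 4 called probe sets of EGR1 and FOS kept their call in 24 of 64 cases and lost it in 40. Of 588 values of named genes under the alternatives, which are mostly of genes not called at the outset, 542 kept their side of the threshold, 34 passed it, all with array weights, and 12 lost it, all of EGR1, and 0 changed sign. With the mean of each gene's probe sets 20 of the 35 named genes had a log2 fold change smaller by over 1.5 times. The same held for 6 of the 35 without control 1 and endosulfan 1, for 6 with the spike-in covariate and for 6 in the like-spike arrays. For the calls that were lost or gained the cause was not tested, and some of these fits also had fewer arrays or residual degrees of freedom. A bound on dim probe sets could not be set, since signal over background was not analysed here.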

Other observations

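The tests of the aminoacyl-tRNA synthetases and of the NRF2 targets were chosen after their members had been seen, and the genes named in this part were picked from their values. Members of the heat shock protein list went both ways, with 11 of 22 on each side and none past the threshold over all genes. The list had a median log2 fold change of -0.01 and a limma camera adjusted p of 0.572. HSP90AA1, the 1 member that was lower when adjusted over the list alone, had a log2 fold change of -1.11.

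The genes were split by genomic length into 4 groups of 4528. In the shortest group, with a median length of 4300 bp, 2.98% of the genes were lower and 9.32% higher at an unadjusted p below 0.05 with limma. In the longest group, with a median of 132464 bp, 19.4% were lower and 3.47% higher. The median difference between control 1 and control 2, which are both untreated with endosulfan, went from -0.13 in the shortest to 0.09 in the longest group.

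A hypothesis from the values of GARS1, CARS1 and NARS1, at log2 fold changes of -1.63, -0.83 and -1.36, was that the cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include several ATF4 targets, fall as a set. Over the other 16 genes, without these 3, 12 were on the lower side and 7 were lower at an unadjusted p below 0.05 with limma, with none higher. IARS1 and RARS1 were at -1.27 and -1.19, each with a limma and Benjamini-Hochberg adjusted p of 0.196 over all genes. The median of the 16 was -0.30, and camera gave p = 0.000608 with the preset correlation and p = 0.0817 with an estimated one, so a fall of the set stays open. With the spike-in level as a covariate the median was -0.11.

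A further hypothesis was that NQO1 is part of a wider rise of NRF2 targets. The 24 other measured targets had a median log2 fold change of 0.10 and a camera p of 0.36 with the preset correlation, which leaves a wider rise undecided. The 95% interval of their mean was -0.23 to 0.28. Without control 1 and endosulfan 1, a selection made after the data were seen, the p was 0.0124 with the preset correlation and 0.261 with an estimated one.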
